A study of Mus musculus with 4 samples.

How the data were processed

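RNA abundance was measured in 4 libraries from megakaryocytes (the bone marrow cells that shed platelets) sorted by flow cytometry from mouse bone marrow, 2 from young and 2 from old animals. The labels give no ages, no sorting gate and no number of animals per library, so the p-values below measure only the spread between these samples, which may be technical. Libraries were made from poly(A)-selected RNA with a strand-specific kit, per the labels' protocols. The submitters' processing notes name Trim Galore, TopHat, STAR and DESeq2 and the genome builds mm9 and GRCm39, without saying which step used which. Gene identities are the symbols in the files, and no coordinates are given because the roles of the builds are not given in the sources used here.

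The deposited TPM table holds TPM values, transcript abundances corrected for transcript length and scaled to a fixed total, for 56793 gene rows, computed by the authors, per the file headers, and each library sums to 1000000. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval or floor is given. The authors' deposited table of changed genes gives a log2 fold change, its standard error, a p-value, an adjusted p-value and a mean normalized count signal for 1255 genes, per the file headers. The table of changed genes also carries columns named for each of the 4 libraries, and the TPM values analysed here were not taken from them. The authors' deposited enrichment tables give log10 p-values and log10 q-values for gene terms, per the file headers. For all 1255 genes the p-value was smaller than the ratio of the fold change to its standard error gives, so the fold change and p-value of a gene in that table do not come from that ratio.

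Genes with a mean of at least 1 TPM over the 4 libraries were kept, which left 16073. Values were transformed to log2(TPM + 1), and folds on this scale understate the change of genes with low values. The old and young groups were compared with limma (version 3.58.1, in R 4.3.3) with moderated variances that follow a trend with mean level, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333. For 22 gene lists and 11 lists of cell type markers, limma's camera compared each list with all other tested genes at a preset correlation of 0.01, adjusted over the 33 lists, and was repeated with a correlation estimated from the data. With 2 residual degrees of freedom that repeat had little power, so failing it does not show that the members of a list vary together. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The lists, tests, rule for named genes and first set of alternatives were fixed before the data were examined. The rule named Pf4, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 10 TPM in the higher group and no overlap between groups, and from each list up to 3 changed members with the smallest p, or up to 2 members as values where none changed. Other genes named were chosen after their values were seen.

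The script was tested on simulated data for the comparison of old with young, over 16073 genes with the means and spread of the real ones and 200 changed genes. It recovered 11.9% of genes changed by 1.5-fold, 43.3% of those changed 2-fold and 78.8% of those changed 4-fold, and 3.3% of its calls were unchanged genes. Of 100 unchanged lists, 2% had an unadjusted p under 0.05, and 100% of 20 lists of 20 genes shifted by 0.5 were called. Simulated genes varied independently and list members were drawn at random, so these rates do not carry over to lists whose members vary together. The changed genes were drawn only from those well above the minimum of 1 TPM in young samples, so recovery nearer it was not assessed. Their changes went up or down at random and the values were not rescaled to a fixed total. The rates therefore do not cover shifts of other genes that a fixed total brings. In the data 3204 genes were called, so recovery and error rates with that many changes were not assessed either.

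Alternatives were other pseudocounts, filters, scalings between libraries, variance models, list tests and thresholds, the replicate number as a block, each library left out in turn, and removal of immunoglobulin, haemoglobin and mitochondrial genes. Removal of immunoglobulin genes alone, a crossed block, a median ratio over tested genes and 4 further gene lists were chosen after seeing the data. Those lists were haem synthesis, proteasome subunits, scavenger receptors of resident macrophages, and anti-inflammatory and negative regulators of cytokine signalling. Transcript lengths for one check came from the GENCODE annotation of another build and were matched by symbol for 1202 of the 1255 genes. Figures were drawn with matplotlib 3.10.9.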

Results

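Gene expression was compared between samples labelled as sorted megakaryocytes of young and old mice, with 2 libraries in each group. The study's title concerns platelet factor 4, the product of Pf4, in the ageing of blood stem cells, so the level of Pf4 in its main source cell was the first question. Between 25933 and 29216 genes were above 0 in each library. Correlations across genes on the log2 scale were 0.988 between the young libraries and 0.980 between the old libraries, against 0.948 to 0.958 between the groups, and genes are not independent replicates. The most abundant transcript in every library was S100a9, a calcium-binding protein of neutrophils, at 59317 and 55649 TPM in the young and 51121 and 49829 TPM in the old libraries. Pf4 ranked 168 and 150 among all genes in the young libraries and 272 and 208 in the old ones. The 16 neutrophil markers summed to 145938 and 139994 TPM in the young and 124401 and 124119 TPM in the old libraries, against 1146 and 1356 TPM and 873 and 1077 TPM for 24 platelet surface receptors. The purity of the sort is not given in the sources used here, so how much of any value below came from megakaryocytes, and how much from neutrophils or other cells, is not known. The columns were assigned to samples by name alone. The authors' table of changed genes carries columns of the same names, but whether these libraries, and no others, lie behind its comparison is open. Immunoglobulin genes made up 1.03% and 0.896% of TPM in the young libraries and 13.3% and 13.1% in the old ones. Because TPM has a fixed total, this share lowers the values of all other genes in the old libraries.

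Pf4, a chemokine stored in platelet granules, was at 789 ± 60.7 TPM (SD, n = 2) in young and 515 ± 116 TPM (SD, n = 2) in old samples. Both old libraries, at 433 and 598 TPM, lay below both young libraries, at 746 and 832 TPM. The log2 change was -0.63 (SE 0.16), with a limma adjusted p of 0.0545, which did not pass the threshold. With the immunoglobulin genes removed and the rest rescaled, the log2 change of Pf4 was -0.44. The change was -0.86 with an adjusted p of 0.0306 without old replicate 2, but -0.40 with an adjusted p of 0.0733 without old replicate 1. With a mean of at least 5 TPM the adjusted p was 0.0430, and over the alternatives the adjusted p of Pf4 ranged from 0.0306 to 0.185. In the authors' deposited table Pf4 had a log2 fold change of -0.38 (SE 0.15) and an adjusted p of 0.0168. Folds over standard errors do not give the p-values of that table, so -0.38 and -0.63 may not be the same measure. Other platelet genes were chosen after their values were seen. Ppbp, another granule chemokine, was at 483 ± 209 TPM (SD, n = 2) in young and 174 ± 95.9 TPM (SD, n = 2) in old samples, with an adjusted p of 0.0798. The adjusted p was 0.295 for Itga2b, the integrin subunit used to mark megakaryocytes, and 0.439 for Vwf, whose log2 change was -0.16 as deposited and 0.02 with immunoglobulin genes removed.

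**Figure D1:**
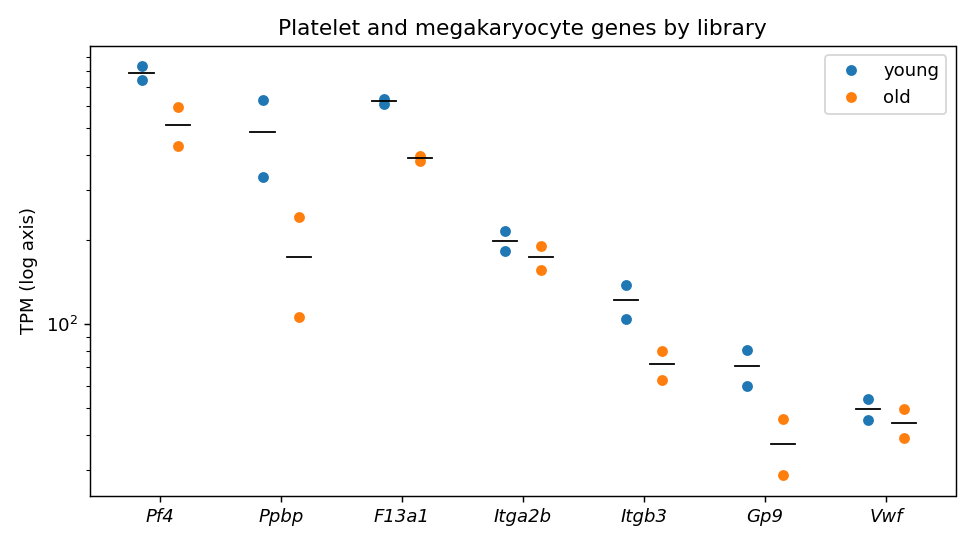
TPM on a log axis of 7 platelet and megakaryocyte genes in each library, with points for the 2 young and 2 old libraries and black bars for group means. Pf4 lay at 746 and 832 TPM in young and 433 and 598 TPM in old libraries, and Itga2b and Vwf overlapped between groups.

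Across the transcriptome, 3204 of 16073 genes changed between old and young, 835 higher and 2369 lower in old. The largest rises belonged to antibody genes. Igkv8-21, a kappa variable gene, rose from 12.04 ± 0.0661 to 5037 ± 513 TPM (SD, n = 2 each), and Ighg2b, Ighg2c, Iglv3, Ighv6-3, Ighv2-5, Igkv14-130 and Ighv2-9 also rose, by 6.10 to 7.52 on the log2 scale. Gm56600 rose by 6.82, and Ighd2-7 was listed at 0 in both young libraries and at 78.9 and 68.7 TPM in the old ones. Of 211 immunoglobulin genes tested, 108 rose and 6 fell. Close members of one immunoglobulin variable gene family can share reads, so values of single members are uncertain. The largest falls were in Ighv5-9, Ubb-ps, the pre-B cell genes Vpreb1a, Igll1 and Vpreb3, the globin genes Hbb-bs, Hbb-bt and Hba-a2, the macrophage gene Cd5l and mt-Ts1. Hbb-bs fell from 4617 ± 30.7 to 1382 ± 214 TPM (SD, n = 2 each). Ubb-ps, a pseudogene that can share reads with Ubb, fell from 110 to 10.4 TPM, while Ubb was at 851 and 829 TPM with an adjusted p of 0.798 and a log2 change of -0.04 as deposited and 0.15 with immunoglobulin genes removed.

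**Figure D2:**
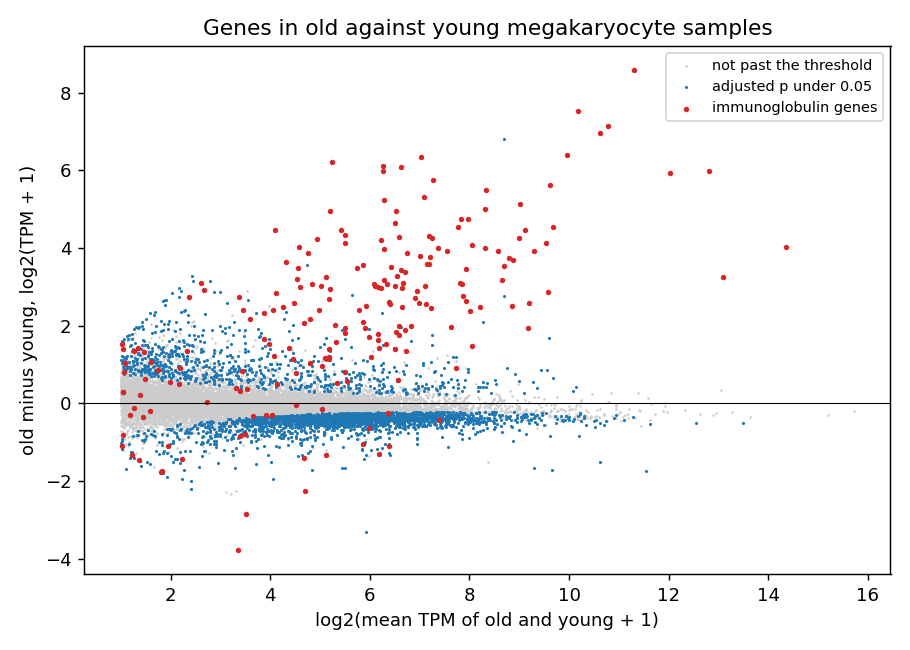
Old minus young difference in log2(TPM + 1) for each of 16073 tested genes against the log2 of their mean TPM plus 1, with immunoglobulin genes in red and other genes past the threshold in blue. Of 211 immunoglobulin genes, 108 rose, and values are as deposited, where 2369 of the 3204 changed genes were lower, against 508 of 1803 with immunoglobulin genes removed.

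The balance of rises and falls depended on the scaling. The median log2 change of all tested genes was -0.10 as deposited, -0.05 after median-ratio scaling and 0.07 with immunoglobulin genes removed. Median-ratio scaling gave 953 higher and 900 lower genes, a median ratio over the tested genes gave 1066 higher and 681 lower, and removal of immunoglobulin genes gave 1295 higher and 508 lower. Of the 2369 genes lower as deposited, 507 were also lower after that removal. The 835 higher ones included 108 immunoglobulin genes that were themselves removed, and the other 727 all stayed higher. Rescaling after that removal raises the remaining genes in old relative to young libraries, so kept rises are no independent check. The count of changed genes was 359 without young replicate 1, 474 without young replicate 2 and 909 without old replicate 1.

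Plasma cell and B cell markers moved apart. All 12 plasma cell markers rose, also adjusted over the list alone, with a camera adjusted p of 2.24e-16. Derl3, an endoplasmic reticulum protein, rose from 3.18 to 48.2 TPM, Tnfrsf17, the BCMA receptor, from 0.760 to 11.8 TPM, and Igkc from 2425 to 39707 TPM. Of 14 B cell markers, 10 fell and 1 rose over all genes, and 11 fell and 1 rose adjusted over the list alone, with an adjusted p of 0.00227. The exception was Ighm, which rose from 1639 to 15710 TPM, while Vpreb3 fell from 67.8 to 20.9 TPM. With an estimated correlation the adjusted p was 0.431 for plasma cells and 0.735 for B cells. No list passed with an estimated correlation, where the smallest adjusted p was 0.431.

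Erythroid and macrophage markers fell. Of 17 erythroid markers 16 fell, in both adjustments (adjusted p = 1.08e-10, and adjusted p = 0.431 with an estimated correlation). Klf1, the erythroid transcription factor, fell from 78.5 to 34.1 TPM and Slc4a1, the band 3 anion exchanger, from 258 to 118 TPM. Of 16 monocyte and macrophage markers 13 fell, and 15 adjusted over the list alone (adjusted p = 9.65e-07, and adjusted p = 0.494 with an estimated correlation). Hmox1, haem oxygenase, fell from 225 to 123 TPM and Vcam1 from 78.8 to 39.0 TPM. With immunoglobulin genes removed, 14 erythroid and 7 monocyte and macrophage markers fell. Among 13 stem and progenitor markers 4 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.0173, and adjusted p = 0.735 with an estimated correlation). Ly6a, the Sca-1 antigen, rose from 24.2 to 125 TPM and Cd48 fell from 212 to 136 TPM, a call not kept under median-ratio scaling (adjusted p = 0.0511). The stem and progenitor list had an adjusted p of 0.353 without old replicate 2, 0.0851 with no filter on low values and 0.0672 with a mean of at least 5 TPM.

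Most immediate early genes and a smaller part of the inflammatory genes rose. Of 21 immediate early genes 17 rose and none fell over all genes, and 18 rose and 1 fell adjusted over the list alone (adjusted p = 3.20e-14, and adjusted p = 0.494 with an estimated correlation). Egr1 rose from 39.5 ± 1.04 to 156 ± 10.5 TPM (SD, n = 2 each), and Nr4a1 from 47.4 to 129 TPM. Of 24 NF-kappaB targets and cytokines 9 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (adjusted p = 6.62e-06, and adjusted p = 0.614 with an estimated correlation). Il1b, encoding interleukin-1 beta, rose from 369 ± 4.09 to 1177 ± 37.0 TPM (SD, n = 2 each), Cxcl2 from 55.4 to 171 TPM and Ptgs2 from 20.8 to 67.4 TPM. Of 24 genes of the unfolded protein response 7 rose and 2 fell, and 8 rose and 5 fell adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.614 with an estimated correlation). Among them Creld2 rose from 65.6 to 118 TPM and Xbp1, which is also high in plasma cells, from 171 to 259 TPM. Of 22 antigen presentation genes 5 rose in both adjustments (adjusted p = 0.0148, and adjusted p = 0.735 with an estimated correlation), and Cd74 rose from 963 to 1291 TPM, a call not kept under median-ratio scaling (adjusted p = 0.0973). Without old replicate 2 the adjusted p was 0.303 for antigen presentation and 0.0866 for the unfolded protein response, and without young replicate 2 it was 0.138 for antigen presentation. With no filter on low values it was 0.126 for antigen presentation and 0.118 for the unfolded protein response, and camera with ranks gave 0.0896 for the latter.

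Proliferation and housekeeping lists fell with the preset correlation, as did the erythroid list, of which 16 of 17 markers fell with a median log2 change of -1.12. In the test of single genes, the pre-B cell genes Vpreb1a, Vpreb3 and Igll1, which mark precursors that also divide, fell too. Of 26 DNA replication genes 23 fell, and 24 adjusted over the list alone (adjusted p = 5.93e-11, and adjusted p = 0.565 with an estimated correlation). Pcna, the polymerase clamp, fell from 444 ± 3.70 to 278 ± 4.68 TPM (SD, n = 2 each), and Rrm1 from 145 to 91.6 TPM. Of 25 G2/M genes 20 fell, and 25 adjusted over the list alone (adjusted p = 6.13e-10, and adjusted p = 0.494 with an estimated correlation), with Ccna2 at 198 and 127 TPM. After removal of immunoglobulin genes 17 DNA replication and 12 G2/M genes still fell. Of 49 nuclear-encoded oxidative phosphorylation genes 40 fell, and 49 adjusted over the list alone (adjusted p = 5.41e-12, and adjusted p = 0.735 with an estimated correlation), and after that removal 3 fell while the list had an adjusted p of 2.13e-14. Of 60 cytosolic ribosomal protein genes 12 fell, and 57 adjusted over the list alone (adjusted p = 2.77e-08, and adjusted p = 0.737 with an estimated correlation), and after that removal 0 fell while the list had an adjusted p of 1.11e-09. Of 15 heat shock genes 9 fell, and 10 adjusted over the list alone (adjusted p = 0.00292, and adjusted p = 0.494 with an estimated correlation), with Hspa8, a constitutive chaperone, at 1012 and 563 TPM. Of 22 cholesterol and lipid synthesis genes 4 fell, and 7 adjusted over the list alone (adjusted p = 0.0257, and adjusted p = 0.735 with an estimated correlation), and the list had an adjusted p of 0.118 after that removal, 0.112 without young replicate 2, 0.0854 without old replicate 1, 0.109 with a mean of at least 5 TPM, 0.106 with quantile normalization and 0.0967 without immunoglobulin, haemoglobin and mitochondrial genes.

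Among the megakaryocyte lists, platelet receptors and the cytoskeleton list fell with the preset correlation. Of 24 platelet surface receptors 5 fell, and 13 adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.885 with an estimated correlation), and after removal of immunoglobulin genes 1 fell while the list had an adjusted p of 0.00166. The receptor list had an adjusted p of 0.679 without old replicate 1 and 0.117 with a mean of at least 5 TPM. Itgb3, the integrin beta 3 subunit, fell from 121 ± 23.9 to 71.6 ± 12.1 TPM (SD, n = 2 each), and Ly6g6f from 23.1 to 7.38 TPM. Under median-ratio scaling the adjusted p was 0.0753 for Itgb3 and 0.0522 for Ly6g6f, and for Itgb3 it was 0.0804 with immunoglobulin genes removed. Of 25 genes of the cytoskeleton and proplatelet formation 9 fell, and 14 fell and 1 rose adjusted over the list alone (adjusted p = 0.00695, and adjusted p = 0.735 with an estimated correlation), but the list had an adjusted p of 0.0629 after that removal, 0.0502 without immunoglobulin, haemoglobin and mitochondrial genes and 0.0680 with a mean of at least 5 TPM. Tpm4 fell from 332 to 237 TPM. Of 22 megakaryocyte transcription factors 6 fell and 2 rose, and 11 fell and 4 rose adjusted over the list alone (adjusted p = 0.225), with Gata1 at 76.5 and 45.7 TPM and Gfi1b, a repressor, at 58.9 and 36.9 TPM. Gata1 and Gfi1b also act in erythroid cells, of whose markers 16 of 17 fell, with a median log2 change of -1.12. Of 21 alpha granule genes 4 fell and 2 rose, and 5 fell and 2 rose adjusted over the list alone (adjusted p = 0.963), with F13a1, a clotting factor subunit, falling from 624 to 390 TPM and Srgn rising from 565 to 747 TPM, with an adjusted p of 0.0510 for Srgn under median-ratio scaling.

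**Figure D3:**
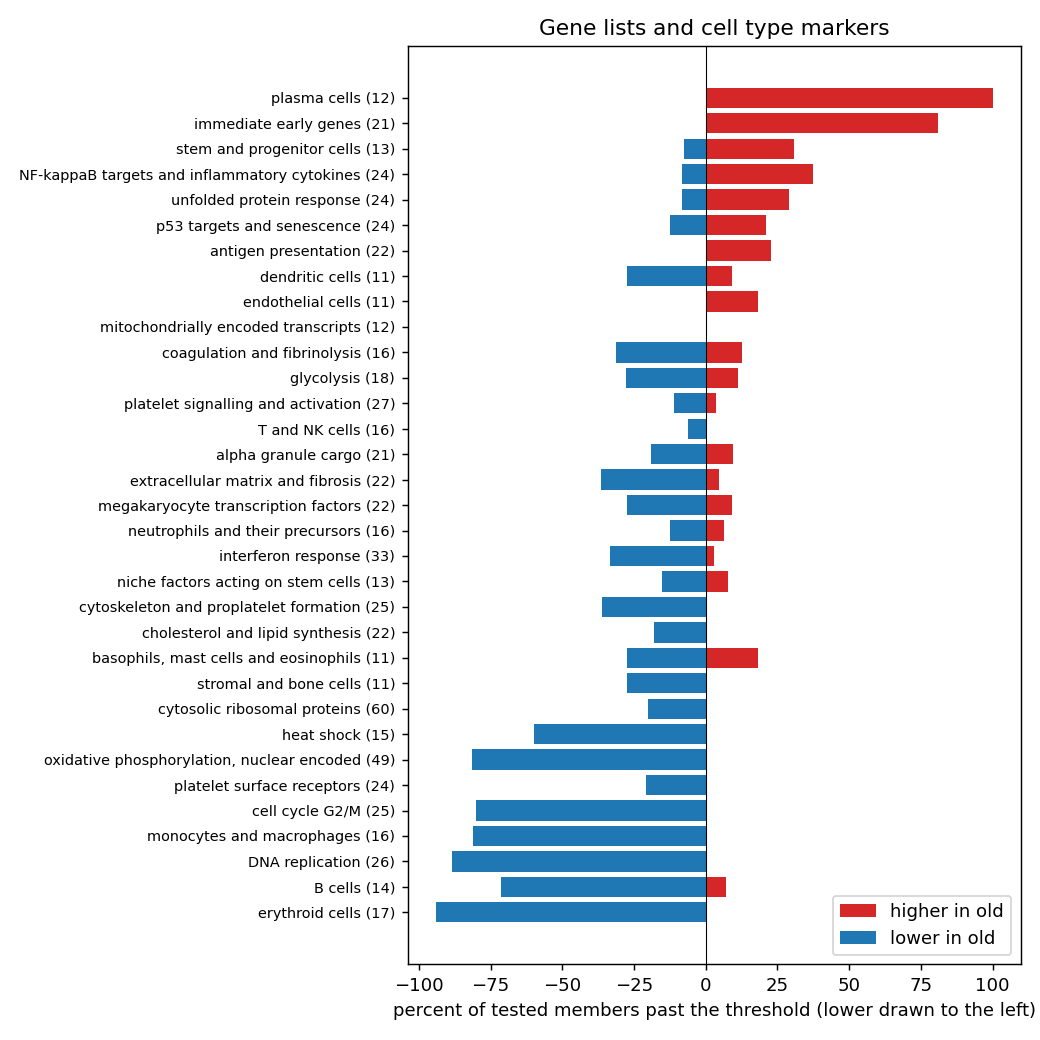
Percent of tested members past the threshold for each of 33 lists, with higher in old drawn to the right and lower to the left, and the number of tested members in brackets. All 12 plasma cell markers rose and 16 of 17 erythroid markers fell in values as deposited, and the 40 falls in oxidative phosphorylation went to 3 with immunoglobulin genes removed.

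The remaining lists did not pass with the preset correlation. The adjusted p was 0.0725 for interferon response, where 11 of 33 genes fell and 1 rose in both adjustments, 0.101 for p53 targets and senescence, 0.294 for platelet signalling, 0.477 for extracellular matrix, 0.645 for glycolysis, 0.852 for mitochondrially encoded transcripts, 0.883 for niche factors acting on stem cells and 0.963 for coagulation. Of 24 p53 targets 5 rose and 3 fell, and 5 rose and 5 fell adjusted over the list alone, with Pmaip1 rising from 11.7 to 30.2 TPM, and the p53 list had an adjusted p of 0.0464 after removal of immunoglobulin genes, 0.0496 after that of immunoglobulin, haemoglobin and mitochondrial genes, 0.0322 with a mean of at least 5 TPM and 0.0452 with quantile normalization. The interferon list had an adjusted p of 0.0241 without young replicate 1 and 0.0373 without old replicate 1, and the endothelial list 0.0428 without old replicate 2. With no filter on low values the adjusted p was 0.000245 for interferon response, 0.00426 for megakaryocyte transcription factors, 0.00421 for platelet signalling, 0.0409 for extracellular matrix and 0.0480 for stromal markers. Of 22 extracellular matrix genes 8 fell and 1 rose, and 10 fell and 2 rose adjusted over the list alone, and Col1a1 fell from 10.6 to 4.11 TPM. Of 18 glycolysis genes 5 fell and 2 rose in both adjustments, as did 5 and 2 of 16 coagulation genes. Of 27 platelet signalling genes 3 fell and 1 rose, with 0 adjusted over the list alone, and 0 of 12 mitochondrially encoded transcripts passed in either. Of 13 niche factors 2 fell and 1 rose, and 4 fell and 3 rose adjusted over the list alone. Tgfb1 fell from 241 to 185 TPM and Il6 rose from 2.03 to 5.95 TPM. The adjusted p of Tgfb1 was 0.0751 under median-ratio scaling and 0.0836 with immunoglobulin genes removed, where its log2 change went from -0.38 to -0.19. For marker lists the adjusted p was 0.118 for endothelial, 0.304 for stromal, 0.858 for T and NK, 0.963 for neutrophil, 0.963 for basophil, mast cell and eosinophil and 0.994 for dendritic cells. Of 11 stromal markers 3 fell, and 4 adjusted over the list alone. Of 11 basophil, mast cell and eosinophil markers 3 fell and 2 rose, and 4 fell and 3 rose adjusted over the list alone. In both adjustments 2 of 11 endothelial markers rose, 3 of 11 dendritic cell markers fell and 1 rose, and 1 of 16 T and NK markers, Gzma, fell. Of 16 neutrophil markers 2 fell and 1 rose in both adjustments, with Camp falling from 7099 to 4955 TPM and Csf3r rising from 639 to 1007 TPM. The adjusted p of Camp was 0.214 under median-ratio scaling and 0.0579 with immunoglobulin genes removed, where its log2 change went from -0.52 to -0.33. In alpha granule, niche factor, endothelial and basophil lists and mitochondrially encoded transcripts camera's direction was up while the median change was below 0.

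The authors' deposited table lists 1255 genes, 527 higher and 728 lower in old, of which 66 and 3 are immunoglobulin genes. Of these 1255, 1233 were tested here, all 1233 had the same direction and 1052 passed the threshold. That table holds only genes past its own threshold and may rest on the same libraries, so the shared direction is no independent check. Fold sizes were close for some named genes, such as Il1b at 1.68 there and 1.67 here. For others they were far apart, such as Ighv2-9 at 0.61 (SE 1.54) and 6.10, and Hbb-bs at -0.56 and -1.75. The strongest groups of terms in the authors' deposited tables were B cell mediated immunity among higher genes (log10 q of -20.4) and Cell Cycle among lower genes (log10 q of -32.5). The normalized means in the authors' deposited table did not track TPM in these libraries. Per TPM and kilobase of transcript, the median log2 normalized mean was 3.18 for 11 plasma cell genes, 3.09 for 13 erythroid genes, 3.08 for 10 B cell genes, 3.22 for 3 neutrophil genes, 4.10 for 5 stem and progenitor genes, 5.24 for 3 endothelial genes and 6.40 for 11 platelet receptors. For Pf4 it was 8.64, from a normalized mean of 129661 and a mean of 652 TPM. The folds and p-values of that table are given as the authors' own. It carries columns named for these 4 libraries, but whether other libraries entered its means is not stated in the sources used here.

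**Figure D4:**
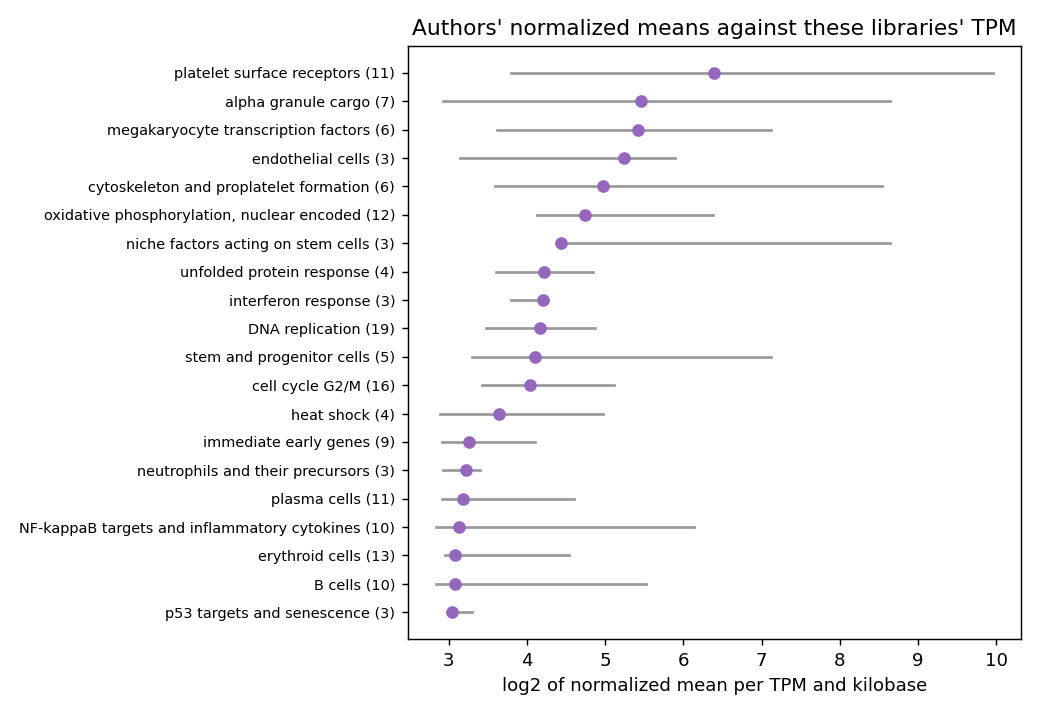
Log2 of the authors' normalized mean per TPM and kilobase for list members in the authors' deposited table, with points for medians, lines from lowest to highest, and the number of genes in brackets. Platelet surface receptors had a median of 6.40 and plasma cells 3.18.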

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

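The removal of immunoglobulin genes alone, the median ratio over the tested genes and the crossed block were chosen after seeing the data. The count of changed genes, 3204 (835 higher, 2369 lower), moved with most settings, and the cause was not tested except where more or fewer genes, libraries or a looser threshold set it. It was 130 (71 and 59) without a filter on low values, 572 (309 and 263) with variances without a trend, 5522 (1545 and 3977) at an adjusted p under 0.1, 1853 (900 lower) with median-ratio scaling, 1747 (681 lower) with the median ratio over the tested genes, 1803 (1295 and 508) without immunoglobulin genes and 1698 (515 lower) without immunoglobulin, haemoglobin and mitochondrial genes. Quantile normalization gave 1289 lower genes. Leaving out a library gave 359 to 2325 changed genes, 233 to 679 higher and 100 to 1646 lower, with the lone library assumed to vary like the pair: 359 without young replicate 1, 474 without young replicate 2, 909 without old replicate 1 and 2325 without old replicate 2.

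The replicate block gave 1252 changed genes (496 and 756) and a Pf4 change of -0.63 that passed, with an adjusted p of 0.0325. The labels do not tie a number to a shared animal or batch, so the numbers were not taken to pair libraries. Deviations of same-numbered libraries had r = -0.146 over all tested genes, but 22 of 24 platelet receptors lay lower in replicate 1 than in replicate 2 in both ages, and that list had an adjusted p of 8.52e-05 under the block. The crossed block gave 4649 changed genes, 1498 of them higher. The log2 change of Pf4 was below 0 in every setting run, from -0.86 to -0.40 with a library left out. Besides the blocks, it passed at -0.63 with a mean of at least 5 TPM (adjusted p = 0.0430), at -0.63 with the looser threshold (0.0545) and at -0.86 without old replicate 2 (0.0306).

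With an estimated correlation 0 of 22 gene lists and 0 of 11 marker lists passed, against 12 and 5 with the preset one. The 2 residual degrees of freedom limit both that estimate and the test built on it. Heat shock did not pass there (camera adjusted p = 0.494), though its estimated correlation of -0.0429 was below the preset 0.01. Failing there thus does not by itself show correlated members. Estimated correlations reached 0.806 for ribosomal proteins and 0.792 for platelet receptors, where correlation may matter more. In the other settings 10 to 14 gene lists and 4 or 5 marker lists passed. None of the 106 genes named by the fixed rule changed direction in any setting that kept it. Ubb and Vwf, outside the rule, did so without immunoglobulin genes. The rule chose most named genes from the same data for large folds or small p-values, so a steady direction was likely in advance. For the 105 named genes other than Pf4, 396 of 1856 alternative values no longer passed, 161 of them with a library left out, and 2 newly passed. These counts include values for Ighm without immunoglobulin genes, which cannot be its own, as it was removed there. Depth is unknown, so what it limits could not be assessed.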

Other observations

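The lists of the first paragraph and the tests of each explanation were chosen after the results were seen. Haem synthesis genes were lower in old samples: 10 of 11 fell, with Alas2, the erythroid first enzyme of the pathway, going from 120 to 47.2 TPM, and 9 fell after immunoglobulin genes were removed. Their median log2 change was -0.73, beside -1.12 for the erythroid markers, of which 16 of 17 fell. Of 31 proteasome subunit genes 30 fell. After immunoglobulin genes were removed 2 fell, while the list had a camera adjusted p of 3.60e-11 at the preset correlation and a median log2 change of -0.17. Of 15 scavenger receptor genes of resident macrophages 10 fell and 2 rose. Cd163, a haemoglobin scavenger, fell from 21.2 to 7.79 TPM and Fcna from 86.0 to 34.0 TPM, while Stab1 rose from 3.17 to 8.08 TPM. Of 16 anti-inflammatory and negative regulators of cytokine signalling 8 rose, among them Dusp5, from 16.2 to 45.9 TPM. The 8 include Nfkbiz, which is not a plain negative regulator and rose from 17.4 to 67.5 TPM. They also include Tnfaip3, of the NF-kappaB list, and Dusp1 and Zfp36, of the immediate early list. With an estimated correlation the adjusted p over these 4 lists was 0.110 for haem synthesis, 0.110 for the proteasome, 0.110 for scavenger receptors and 0.207 for the negative regulators. Xist was at 49.1 to 165 TPM and Ddx3y at 0.322 to 0.508 TPM in the 4 libraries.

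Plasma cell genes were higher in old samples. RNA from plasma cells may account for the rise, as all 12 of 12 markers rose, 8 of them not immunoglobulin genes. The sorting gate is not given and neutrophil markers were abundant in all 4 libraries, so whether the sort removed plasma cells is not known. The old libraries may also come from shared animals: their variable gene usage overlapped by 0.862 for heavy and 0.841 for kappa chains on a scale where 1 is identical, against 0.611 and 0.683 in the young libraries. Between old and young libraries the overlap was 0.393 to 0.484 for heavy and 0.487 to 0.533 for kappa chains. In the old libraries Ighv7-1 held 36.0% and 35.8% of heavy chain variable gene TPM, and Igkv15-103 held 36.8% and 37.6% of kappa. Both genes also led in young replicate 2, at 10.4% and 13.4%. Whether separate animals share usage, or whether the lower levels in young libraries set their overlap, was not tested. An effect of age itself stays open and untested.

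As a list, platelet receptors were lower in old samples with the preset correlation (adjusted p = 0.0281) but not with an estimated one (adjusted p = 0.885). Singly, 5 of 24 members passed and 1 did with immunoglobulin genes removed, and neither Pf4 nor the alpha granule and platelet signalling lists passed. A lower share of megakaryocyte RNA stays open. With immunoglobulin genes removed 3 of 11 marker lists fell, but this could not decide it. The 45 platelet genes held 0.345% to 0.498% of TPM and are only a part of megakaryocyte RNA, whose whole share is not known. How far its loss would move other markers is thus not known either. Whether a common factor set the receptor folds could not be decided. The folds of the 24 receptor genes varied 7.55 times as much as replicates, above a 95% point of 1.77. But a common factor need not give equal folds, as log2(TPM + 1) understates those of low genes and other cells may express some. The spread of replicates may also be technical. Platelet RNA that varies between libraries whatever their age cannot be told apart from age, which stays open, with 2 libraries per group: across 45 genes the fold followed the difference between old replicates with r = 0.791 and between young replicates with r = 0.415, against 95% points of 0.730 and 0.625 in 1000 random lists.

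Platelet genes were high in the authors' deposited normalized means relative to TPM. Although that table carries columns named for these 4 libraries and no others, means over them alone were argued against. Only genes in that table entered the medians, and how this selection shaped them was not tested. Over all 1202 genes with a transcript length the median was 4.10 on the log2 scale. The medians of platelet receptors and plasma cell genes, 6.40 and 3.18, lay 3.22 apart on that scale. Transcript length was argued against for receptors, as the longest transcripts left 3.27, and for Pf4, left 5.29 above the plasma cell median, but it may account for the alpha granule median, whose distance fell from 2.28 to 0.775. Further libraries with more megakaryocyte RNA in those means are a candidate explanation that stays open, since the medians of the 6 marker lists in the table spread over 2.16, with platelet receptors 1.16 above the highest, that of endothelial cells. No biological explanation was tested.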
